A study of Mus musculus with 319 samples.

How the data were processed

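RNA from muscle of F2 mice was measured on 319 2-colour arrays. The animals came from an intercross of C57BL/6J and C3H/HeJ, both lacking functional ApoE, and included both sexes. They were kept on a Western diet rich in fat between weeks 8 and 24. Per the labels, RNA of each animal carried Cy3 and was compared with a common pool in Cy5 made from equal portions of RNA of all samples. The series design names 319 mice and the sample descriptions name 330. The labels give no genotype, treatment group, hybridization date or batch for any animal and a sex, male, for only 1, so all arrays formed 1 group of F2 muscle, with each animal as a replicate. No group comparison was made and no array was assigned a sex or a genotype. The animal numbers ran from 1 to 359. For 1 sample the title gives number 399 and the source name 339, and the latter was used.

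The deposited table holds 1 log10 ratio per probe and array for 23382 probes, which was converted to a log2 ratio for all results. The labels state neither the base of the logarithm nor the direction of the ratio. Both were derived from the data. The values end at exactly -2 and 2, which is a 100-fold ratio in log10 units, and the direction came from the Y-linked genes, as given with the results. How image values were background-corrected, normalised, limited or left blank before deposit is not given in the sources used here. The array medians lay between -0.08 and 0.14 on the log2 scale, so the arrays had not been centred at exactly 0. For arrays no count of molecules exists, and the number of arrays limits the precision.

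The platform table gave 1 gene symbol for 13639 probes, several for 48 and none for 9695. Names were kept for 12648 probes of 10832 genes whose gene ID was found in the RefSeq table of the mouse assembly GRCm38.p6. For 991 probes the ID was not found there. That table served for current names and for the order of genes along chromosomes only. The genome build behind the probe design is not given in the sources used here. Probes with a value on at least 80% of arrays were tested, which kept 23190 probes of 10756 genes and left out 192. Remaining blanks were treated as missing. Of the pair of arrays that share animal number 227, neither was the array most correlated with the other (r = 0.587, against 0.660 and 0.772 with other arrays), so both were kept under the rule set for them. One of the pair is listed between numbers 326 and 328, so its number may be a misprint. Both were placed at 227 wherever animal number was used.

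The design, the 35 gene lists with 502 genes and the other settings to try were fixed before the data were examined. Of these lists, 31 entered the coherence test. The X inactivation, Y-linked and parental strain lists had been left out of it by design, and the fast fibre list had 1 measured gene, under the 5 required. Probes of the same gene were averaged for list scores and for neighbouring genes. Coherence was the mean pairwise Pearson r of a list's genes across arrays, tested one-sided against 10000 random lists drawn from the same deciles of SD. A list score was the mean of the z-scored genes. Pairs of scores were compared by Pearson r and Spearman rho with two-sided permutation tests of 100000 resamples, and r was computed again without the 2 arrays farthest from the median of the first score. The share of 10000 pairs of random lists with as large a correlation was given beside it. Each score was split in 2 where the sum of squares between groups was largest, with at least 15 arrays on each side. The point of the split is called the gap. Where the group means differed by more than 4 within-group SDs, the score was taken to fall in clusters. Correlations were then computed within each cluster. Such a split can also cut a long tail that has no empty interval. The value of 4 was chosen after the data were seen. In 2000 simulated normal samples the highest separation was 3.25, and skewed samples were not simulated. The interferon response (3.78) and erythroid (3.39) scores lay between 3.25 and 4 and were counted as without clusters. The erythroid score was not split.

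For the macrophage, adipocyte, slow fibre and clock activating arm scores, limma fitted the log2 ratio of each probe on the score, with the members of the list left out. Slopes are log2 units per 1 SD of the score. Benjamini-Hochberg adjusted p values were compared with a threshold of 0.05, and probes with an absolute r over 0.5 were also counted. Each score was shuffled 100 times. It was also shifted 100 times along animal number by at least 20 places with the ends joined, which keeps neighbouring animals together and was chosen after the data were seen. For each probe, an equally spaced mixture of 3 normal components with weights 1:2:1 was compared with 1 normal distribution. A probe was called where the BIC improved by over 10 and the spacing was over 3 component SDs. Neighbouring genes were compared by the mean absolute r of pairs at set distances in gene order, one-sided, against 1000 permutations of gene positions. The alternatives to this last test used 100 permutations each.

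Named genes followed a fixed rule. It took the 10 genes with the largest positive and the 10 with the largest negative moderated t for each score, the 3 best and the least correlated members of coherent lists, the 20 genes of largest SD, the 15 called genes with the largest BIC gain, all genes of the parental strain list, the Y-linked genes and Xist, and the 5 highest and 5 lowest pairs of list scores. The pairs were ranked over all scores and, after the data were seen, again over the scores without clusters. Genes named outside this rule are given as such.

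The other settings were subtraction of each array's median, quantile normalization, leaving out 20 arrays of outlying SD (over 3 scaled MADs from the median), only the 20457 probes with a value on every array, no filter beyond 20 arrays with a value, the mean Y-linked level as a covariate, removal of the first principal component of all probes, blocks of 40 animal numbers as a covariate, the probe of largest SD for each gene, a robust limma fit, the first principal component of a list as its score, random lists not matched on SD, Spearman correlation, the scaled MAD in place of the SD, other limits and free weights for the mixture, and neighbouring genes without pairs sharing the first 3 letters. For the scaled MAD, the range was taken as that of a normal distribution. Xist was also planned as a covariate but no named probe measured it. Chosen after seeing the data were the arrays below the gap in the lymphocyte score, those on each side of the gap in the interferon response score, leaving out probes with values at both limits, and a mixture of 2 equal components.

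The procedures were tested on simulated data. Of 50 simulated lists without correlation 2 were called, and all 50 were called at each built-in r of 0.1, 0.2 and 0.4. The pair test called 45% of 20 pairs built with r 0.2 and 0% of 760 built without. The limma fit recovered 0%, 50%, 96% and 100% of 50 probes built with r of 0.1, 0.2, 0.3 and 0.5, and called 0.0261% of 22974 unchanged probes. Apart from the built-in r, these probes were drawn independently of each other and of animal number. Their rates therefore do not cover variation shared by many probes or along animal number. The mixture called 0 of 3000 normal, 0 of 3000 skewed and 0 of 3000 heavy-tailed probes, 2.55% of 2000 built as 1:2:1 at a spacing of 2.5 SDs, and 99.1% at 3.5 SDs. Without a shared factor, adjacent simulated genes had a mean absolute r of 0.0450 against 0.0448 for other chromosomes (permutation p = 0.376). With factors shared in blocks of 20 genes it was 0.192. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1, numba 0.67.0, matplotlib 3.10.9, R 4.3.3, limma 3.58.1 and statmod 1.5.0.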

Results

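Muscle RNA of F2 mice from C57BL/6J and C3H/HeJ parents, both without functional ApoE, was compared with a pool of all samples on 319 arrays. The series keywords name the genetics of gene expression as its subject, so the measurements described here concern how transcripts varied between animals of 1 group. The arrays gave 23382 log2 ratios each, of which 0.654% were missing. The SD of the ratios on an array ranged from 0.213 to 1.08, with a median of 0.36. The array medians ranged from -0.08 to 0.14. Over 50721 pairs of arrays the correlation across probes ranged from -0.638 to 0.891 with a median of 0.339. It was under -0.3 in 5078 pairs. Probes are not independent replicates. At the limits of the deposited scale lay 1871 values below and 1808 above, and 434 probes reached both limits.

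The Y-linked genes gave the direction of the ratios. Eif2s3y, which encodes a subunit of a translation initiation factor, lay at a median log2 ratio of -5.62 (SD 0.61) on 164 arrays and at 1.08 (SD 0.48) on 155 arrays, with no values between -3.71 and -0.79. Kdm5d, a histone demethylase, lay at -2.77 (SD 0.66) on 165 arrays and at 0.92 (SD 0.40) on 154 arrays. The genes placed 318 of the 319 arrays on the same side. A gene present in 155 or 154 of 319 equal portions of a pool would stand 1.04 or 1.05 above that pool in the carriers, and the upper groups lay near these values. The long side was the lower one, so a positive ratio meant more RNA in the animal than in the pool. Across probes the mean ratio fell with the variance, with a slope of -0.218 (bootstrap SE 0.0227, 200 resamples), against -0.347 for normally distributed log2 ratios over an arithmetic mean. Xist, the transcript that silences an X chromosome in females, had no named probe, so the X inactivation list was not measured.

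Most of the 20 named genes of largest SD had values at both limits of the scale. The SD across 319 arrays was 3.26 for Eif2s3y, 2.25 for Skap2, an adaptor protein of immune cells, and 2.16 for Cd22, a receptor of B cells. The other 17 of the 20 named genes of largest SD, led by Olfr707 with an SD of 3.15 on 306 arrays, Nlgn1 with 2.74 on 316 and Lhx1 with 2.70 on 309, had values at both limits of the scale. Chosen after the values were seen, the next genes without such values included Ngp, a protein of neutrophil granules, with an SD of 1.88, the macrophage elastase Mmp12 with 1.88, the chemokine receptor Ccr6 with 1.78, the B cell chemokine Cxcl13 with 1.71, the fatty acid binding protein Fabp1 with 1.68 and the protease inhibitor Slpi with 1.66. For Cd22, Ccr6 and Cxcl13 the spread came with 57, 56 and 58 arrays that stood above a gap. Over all probes the median SD was 0.23, with the 5th percentile at 0.12 and the 95th at 0.69. The range between the 5th and 95th percentiles of arrays was over 1 log2 unit for 5433 of 23190 probes (23.4%) and over 2 for 1018. Of the 433 tested probes at both limits the median SD was 1.05. For 1144 genes with at least 2 probes, the median r between probes of the same gene was 0.171 (quartiles -0.0265 and 0.456) across animals, against 0.00595 for random pairs of probes. It was over 0.5 for 22.3% of these genes and negative for 332, so a single probe was a poor measure of many genes. No test was made of these values.

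Among the lists whose arrays did not fall in clusters, genes of slow muscle fibres varied together most closely. The 11 measured slow fibre genes had a mean pairwise r of 0.748 across 319 arrays, led by the troponins Tnnt1 (mean r with the other members 0.844) and Tnnc1 (0.836) and the myosin light chain Myl2 (0.838), with the calcium store protein Casq2 lowest at 0.419. The 16 macrophage genes had a mean r of 0.672, led by the Fc receptor chain Fcer1g (0.786), the protease Ctss (0.778) and the adaptor Tyrobp (0.772), with Cd68 lowest at 0.357. The 19 interferon response genes reached 0.548, led by Stat2 (0.684), Psmb9 (0.662) and Ifit3 (0.658), with Rsad2 lowest at 0.223. For all of these the random lists gave p = 1e-04, the smallest that 10000 lists can give, and an adjusted p of 0.000258.

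Metabolic, extracellular matrix and adipocyte genes also moved as groups. The 11 glycolysis and glycogen genes had a mean r of 0.516, led by the glycolytic enzymes Aldoa (0.643), Pfkm (0.637) and Pkm (0.624), with Pgk1 at 0.160. The 19 extracellular matrix genes reached 0.491, led by Col5a1 (0.640), Col6a2 (0.609) and Sparc (0.586), with Bgn at 0.101. The 7 oxidative phosphorylation genes reached 0.457, led by Ndufs1 (0.581), Cox7a1 (0.564) and Ndufa2 (0.490), with Ndufv1 at 0.20. The 14 fatty acid oxidation genes reached 0.368, led by Acadl (0.529), Fabp3 (0.499) and Acadm (0.490), with Acads at 0.0303. The 15 adipocyte genes reached 0.310, led by the lipogenic enzymes Scd1 (0.527) and Fasn (0.518) and the lipid droplet protein Plin1 (0.520), while Cebpa lay at -0.0927. Named outside the fixed rule, Lep (0.0113), Retn (-0.0472) and Car3 (0.0606) also hardly followed the other members.

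Among the smaller correlations, both lists of circadian clock genes were past the threshold. The 5 genes of the activating arm had a mean r of 0.256 (adjusted p = 0.00674), led by Nfil3 (0.388), Arntl (0.299) and Cry1 (0.279), with Npas2 at 0.0774. Nfil3 and Cry1 are known as repressors, unlike Arntl and Npas2, so the name of the list does not describe all its members. The 8 genes of the repressed arm had 0.155 (adjusted p = 0.00604), led by Dbp (0.297), Bhlhe41 (0.240) and Per3 (0.186), with Nr1d1 at 0.0407. The call of the repressed arm ended with array medians subtracted (mean r 0.0820) and on the arrays below the lymphocyte gap (0.0473), and its sign turned with the first principal component removed (-0.00339), which also ended that of the activating arm (0.0853). The remaining lists past the threshold were erythroid (0.301), proteasome (0.296), ribosomal protein (0.294), glucocorticoid response (0.266), smooth muscle (0.248), nerve and Schwann (0.235), heat shock (0.195), endothelial (0.186), regeneration (0.171) and immediate early (0.101). With the probe of largest SD for each gene, heat shock fell to 0.0965 and was no longer called.

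The lymphocyte, MHC class II, neutrophil, keratinocyte and cell cycle scores passed the same test, but their arrays fell in clusters, so their mean r is given within them. The lymphocyte genes had a mean r of 0.403 on the 260 arrays below the gap and 0.433 on the 59 above it. MHC class II genes, which present antigen, had 0.331 on 264 and 0.562 on 55 arrays. Neutrophil genes had 0.166 on 282 and 0.506 on 37 arrays, keratinocyte genes 0.0557 on 284 and 0.271 on 35, and cell cycle genes 0.113 on 267 and 0.327 on 52. In all, 25 of 31 lists passed. The others were brown adipocyte (mean r 0.215, adjusted p 0.0905), atrophy (0.0859, 0.105), cholesterol synthesis (0.0368, 0.135), oxidative stress (0.0329, 0.184), unfolded protein response (0.0278, 0.291) and denervation (0.0144, 0.334). Brown adipocyte passed with random lists not matched on SD (adjusted p = 0.0379), with quantile normalization (0.0408), with the first principal component removed (0.0367) and on the arrays below the lymphocyte gap (0.0212). Cholesterol synthesis passed with array medians subtracted (0.0390), with quantile normalization (0.0182), with the component removed (0.0436) and on the arrays below that gap (0.0203). Atrophy passed with quantile normalization (0.0482) and without the arrays of outlying SD (0.0435). Of the fast fibre list, 6 of 7 probes lacked values on most arrays, so only 1 gene was measured and the list was not tested.

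**Figure D1:**
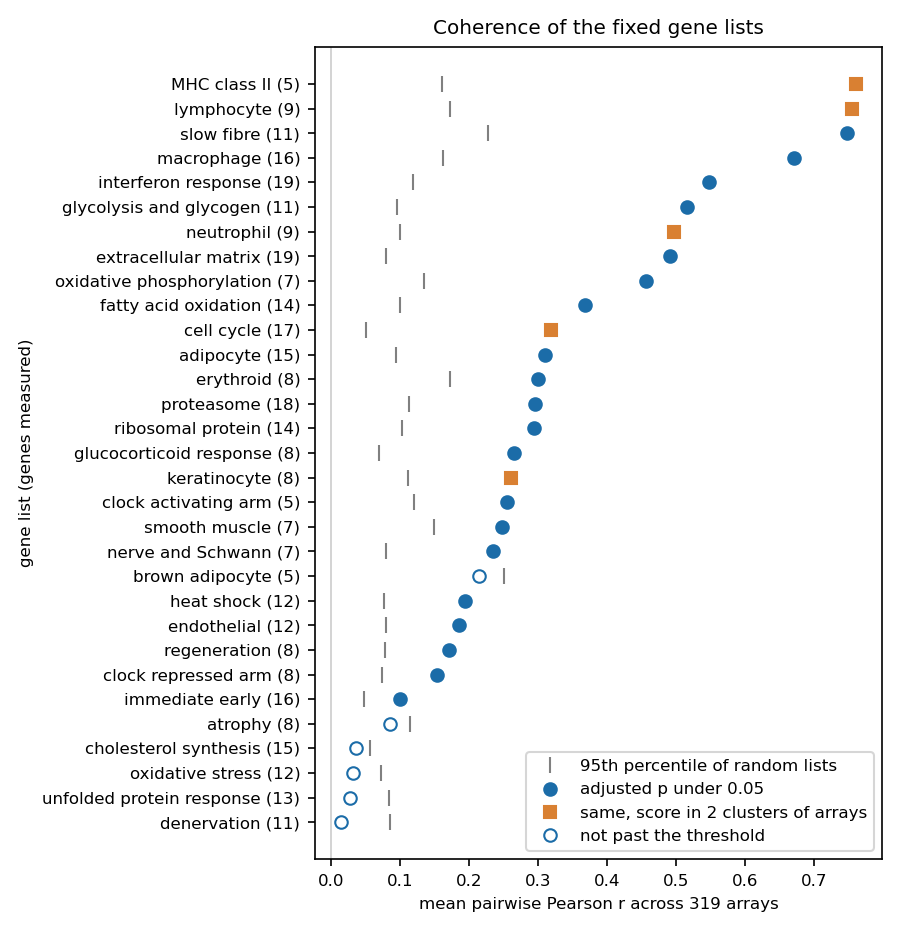
Mean pairwise Pearson r across 319 arrays for 31 gene lists, with grey ticks at the 95th percentile of random lists of the same size and SD. Filled circles mark lists past the threshold, orange squares the 5 of these whose arrays fell in clusters, and open circles the 6 lists not past it. The slow fibre list reached 0.748 without clusters.

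Interferon response and macrophage scores rose together, and both ran opposite to the repressed arm of the clock. Over 319 arrays the macrophage score had r = 0.779 (rho 0.694, r 0.761 without the 2 farthest arrays) with the interferon response and r = -0.701 (rho -0.616, without them -0.690) with the clock repressed arm. The interferon response had r = -0.659 (rho -0.543, without them -0.634) with the clock repressed arm. This was not particular to the repressed arm. With the clock activating arm score, 16 of 16 macrophage and 18 of 21 interferon response probes were lower too. Of the repressed arm probes, 7 of 9 were higher with that score, so the arms did not run opposite to each other. The interferon response score was separated by 3.78 SDs, under the limit of 4 but over the 3.25 of normal samples, so its relations were also computed on each side of its gap, a choice made after the data were seen. With macrophage it had r = 0.493 (rho 0.487, without them 0.488) on 259 arrays below and 0.627 (rho 0.627, without them 0.574) on 60 above. With the clock repressed arm it had r = -0.310 (rho -0.320, without them -0.297) below and -0.506 (rho -0.526, without them -0.423) above. The permutation p was 1e-05 (adjusted 1.33e-05) for r in each but the last, where it was 3e-05 (adjusted 3e-05), and 1e-05 for each rho (adjusted 1e-05). Over all 319 arrays, energy metabolism and regeneration scores were lower where the macrophage score was higher. Glycolysis and glycogen had r = -0.619 (rho -0.547, without them -0.624) with macrophage, oxidative phosphorylation -0.596 (rho -0.505, without them -0.594), and regeneration -0.592 (rho -0.525, without them -0.586). Oxidative phosphorylation went with proteasome at r = 0.712 (rho 0.624, without them 0.677) and with fatty acid oxidation at 0.655 (rho 0.600, without them 0.624), and glycolysis with the clock activating arm at 0.625 (rho 0.544, without them 0.615). Adipocyte and macrophage scores had r = 0.585 (rho 0.601, without them 0.574).

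Over all arrays each of these relations had a permutation p of 1e-05 for r and for rho, the smallest that 100000 resamples can give, and adjusted p of 2.11e-05 for r and 2.26e-05 for rho over 300 pairs. Of 190 pairs of the 20 scores without clusters, 142 passed the threshold, 80 of them positive and 62 negative. Random lists gave as large an r in under 5% of draws for 23 of the 190, and for adipocyte with macrophage in a share of 0.225. With the first principal component removed, the calls of macrophage with glycolysis (r -0.00248), with oxidative phosphorylation (-0.110) and with the clock repressed arm (-0.0473), and that of the interferon response with the clock repressed arm (-0.0368), ended.

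**Figure D2:**
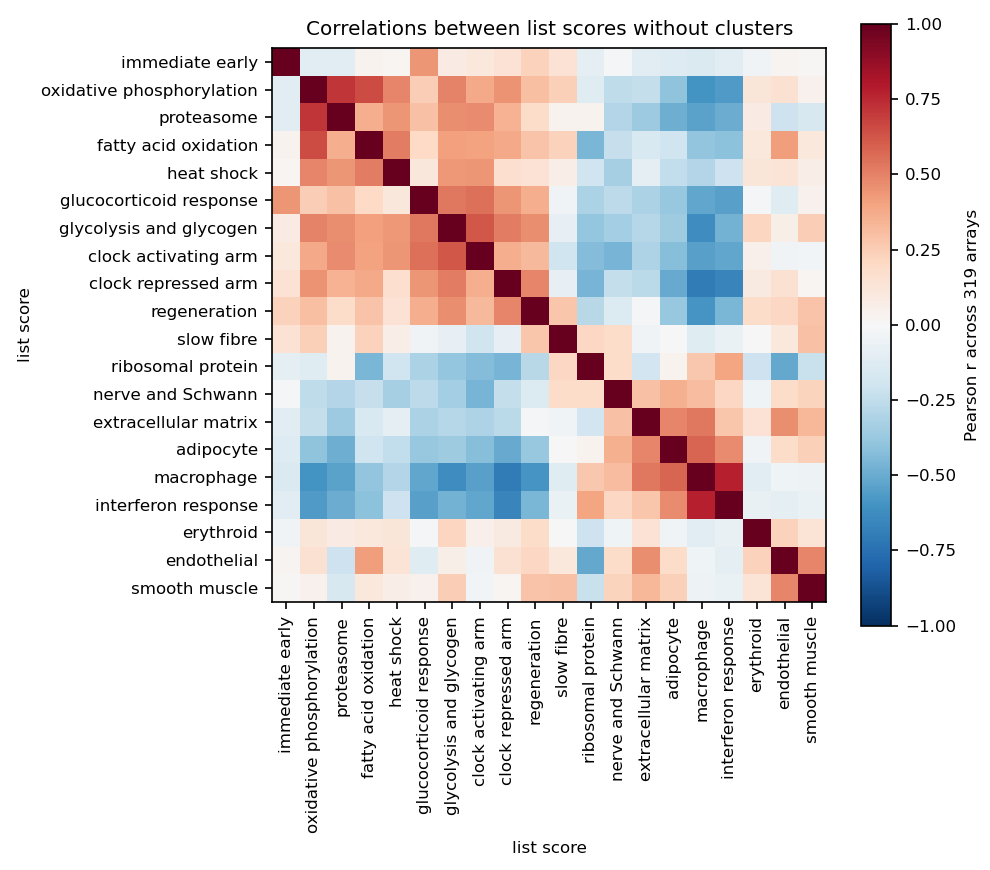
Pearson r between the 20 list scores whose arrays did not fall in clusters, over 319 arrays, with colour from negative to positive r. Macrophage and interferon response scores (0.779) and oxidative phosphorylation and proteasome scores (0.712) stand out as positive, macrophage and clock repressed arm scores (-0.701) as negative.

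For scores in clusters, 220 correlations were computed, 110 on each side of the gap. MHC class II rose with macrophage on both sides (r 0.740, rho 0.734 and r 0.732 without the 2 farthest of 264 arrays below; r 0.736, rho 0.742 and 0.704 of 55 above). It also rose with the interferon response (r 0.539, rho 0.522, without them 0.531 below; r 0.703, rho 0.678, without them 0.616 above). Lymphocyte and MHC class II scores had r = 0.349 (rho 0.305, without them 0.294) on the 260 arrays below the lymphocyte gap and 0.729 (rho 0.735, without them 0.718) on the 59 above. These 6 correlations each had a permutation p of 1e-05, the smallest possible, with adjusted p of 6.29e-05 for r and 6.87e-05 for rho. MHC class II with cell cycle had r = 0.231 below (p = 9e-05, adjusted p = 0.000388; rho 0.316, p = 1e-05, adjusted 6.87e-05; 0.209 without them) and r = 0.637 above (p = 1e-05, adjusted p = 6.29e-05; rho 0.669, p = 1e-05, adjusted 6.87e-05; 0.589 without them).

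Glycolysis ran opposite to lymphocyte on both sides, with r = -0.385 below (p = 1e-05, adjusted p = 6.29e-05; rho -0.324, p = 1e-05, adjusted 6.87e-05) and r = -0.403 above (p = 0.00144, adjusted p = 0.00453; rho -0.387, p = 0.00265, adjusted 0.00757). Without the 2 farthest arrays r was -0.365 and -0.260. Glycolysis with MHC class II had r = -0.290 below (p = 1e-05, adjusted p = 6.29e-05; rho -0.273, p = 2e-05, adjusted 0.00011; -0.296 without them) and -0.315 above (p = 0.0198, adjusted p = 0.0431; rho -0.503, p = 0.00012, adjusted 0.000508; -0.365 without them). MHC class II with the clock repressed arm had r = -0.294 below (p = 1e-05, adjusted p = 6.29e-05; rho -0.324, p = 1e-05, adjusted 6.87e-05; -0.263 without them) and -0.579 above (p = 2e-05, adjusted p = 0.000116; rho -0.590, p = 1e-05, adjusted 6.87e-05; -0.501 without them). The clock repressed arm with cell cycle had r = -0.320 on 267 arrays below (p = 1e-05, adjusted p = 6.29e-05; rho -0.275, p = 2e-05, adjusted 0.00011; -0.303 without them) and -0.484 on 52 above (p = 0.00036, adjusted p = 0.00139; rho -0.512, p = 0.00015, adjusted 0.0006; -0.530 without them). In all 60 of 110 relations below and 44 of 110 above passed the threshold. Of 27 pairs past it on both sides, 24 had the same sign. Over all arrays, the sign of MHC class II with glycolysis, with the clock repressed arm and with cell cycle, and of the clock repressed arm with cell cycle, turned with the first principal component removed.

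The macrophage score was followed by genes in both directions. Per 1 SD of the score over 319 arrays, the Fc receptors Fcgr3 and Fcgr1 were higher by 0.62 ± 0.013 (SE) and 0.73 ± 0.018 log2 units, complement factor Cfb by 0.85 ± 0.021, the actin-binding Cotl1 by 0.85 ± 0.020 and the surface receptor Slamf8 by 0.98 ± 0.024. The other named genes higher with the score were Dok2, Igsf6, Ctsh, Tmem176b and Slc9a9, with slopes from 0.45 to 0.65. Lower with it were Nme6, Ksr2, Cacng5, Rps6kb2, Nags, Alppl2, Rab25, Rph3a, Kirrel3 and Casc1, by small slopes from -0.083 for Rab25 to -0.14 ± 0.0076 for Rph3a. The adjusted p was at most 3.58e-48 for all of these. With the first principal component removed, the calls of Nme6 (-0.023), Nags (-0.0011) and Casc1 (-0.018) ended.

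Of the fixed lists, 19 of 21 interferon response probes, 5 of 5 MHC class II probes, 18 of 21 extracellular matrix probes and 10 of 17 adipocyte probes were higher with the macrophage score, with the same counts adjusted over the list alone. Lymphocyte probes were higher in 9 of 10 cases, and in 10 adjusted over the list alone, and cell cycle probes in 17 of 24 by either count. Lower were 62 of 66 glycolysis and glycogen probes, 10 of 10 of oxidative phosphorylation, 15 of 17 of fatty acid oxidation and 24 of 27 of the proteasome, again with the same counts adjusted over the list alone. Here and with the other scores, the 66 probes measured 11 genes and the 10 probes 7, so probes are not independent members of a list. Over all probes 17493 of 23174 passed the threshold, 4903 higher and 12590 lower, so that 28.0% were higher. With array medians subtracted, 6960 were higher and 8680 lower, which is 44.5% higher. An absolute r over 0.5 was reached by 3477 probes, 1818 positive and 1659 negative. These were 179 and 1 with the first principal component removed, which left 8113 past the threshold, 885 and 14 on the 260 arrays below the lymphocyte gap, 2321 and 462 with array medians subtracted, 1740 and 832 with quantile normalization, and 2038 and 2489 without arrays of outlying SD.

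The 10 genes named as higher with the adipocyte score had slopes from 0.31 to 0.81. Over 319 arrays, the liver isoform of glycogen synthase Gys2 was higher by 0.74 ± 0.023 (SE) per SD, the antigen-presenting Cd1d1 by 0.81 ± 0.026, the aldehyde dehydrogenase Aldh1a7 by 0.70 ± 0.023, the amine oxidase Aoc3 by 0.68 ± 0.022 and Klb, a co-receptor of FGF21, by 0.61 ± 0.019. Also higher were Fads3, Nnmt, Slc1a5, Car5b and Slc25a10, with slopes from 0.31 to 0.61. Lower were Psmd7, Paip2b, Rab25, Tlk2, Lrrc8d, Prkcq, Rps25, Ubr3, Zscan12 and Chtop, with slopes from -0.066 for Rab25 to -0.12 ± 0.0093 for Paip2b. All had an adjusted p of at most 2.23e-24. Markers of other cells moved with this score. All 16 of 16 macrophage probes, 17 of 21 extracellular matrix probes, 17 of 21 interferon response probes, 9 of 10 lymphocyte probes and 5 of 5 MHC class II probes were higher, and 58 of 66 glycolysis and glycogen probes, 25 of 27 proteasome probes and 10 of 10 oxidative phosphorylation probes were lower, with the same counts adjusted over the list alone.

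Over all probes 15389 of 23173 passed the threshold with the adipocyte score, 4215 higher and 11174 lower. The share higher was 27.4%, and 44.4% with array medians subtracted (5925 higher and 7407 lower). An absolute r over 0.5 was reached by 866 probes, 781 of them positive, and by 743 of these also with the macrophage score. That count was 1784 with the list's first principal component as the score, 1390 with array medians subtracted, 574 with quantile normalization and 210 with the first principal component of all probes removed. The last setting left 5793 probes past the threshold. On the arrays below the lymphocyte gap 9558 passed it and 474 had an absolute r over 0.5.

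Genes were both higher and lower with the slow fibre score. Per SD over 319 arrays, Spred2, an inhibitor of Ras signalling, was higher by 0.57 ± 0.014 (SE), the esterase Ces5a by 0.50 ± 0.024, the small GTPase Rab15 by 0.43 ± 0.025, the LIM domain proteins Pdlim1 by 0.37 ± 0.016 and Csrp1 by 0.35 ± 0.018, Ldhb, the lactate dehydrogenase subunit of oxidative tissues, by 0.34 ± 0.017 and Lmod2, which elongates thin filaments, by 0.29 ± 0.018. Ift81, Erf and Cyp2c29 were higher by 0.35, 0.21 and 0.17. Lower were Tiam1, an activator of Rac, by -0.42 ± 0.039, Dkk3, of the Dickkopf family, by -0.39 ± 0.046, and Gdap1, Igfbp5, Twist1, Srebf1, Zfp296, Rab40b, Slc8a1 and Plcl2, with slopes from -0.22 to -0.080. All had an adjusted p of at most 3.82e-11. Of fatty acid oxidation probes 9 of 17 were higher, and 13 adjusted over the list alone. For oxidative phosphorylation these counts were 3 of 10 and 7, for ribosomal proteins 12 of 53 and 16, and for smooth muscle 5 of 7 by either count. Of glycolysis and glycogen probes 1 of 66 was higher and 2 were lower (1 and 1 adjusted over the list alone).

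Far fewer probes passed with the slow fibre score than with the others in these counts, 3265 of 23175, with 1697 higher and 1568 lower. An absolute r over 0.5 was reached by 69, of which 67 were positive. Of these 69 probes, 2 were also among those of the macrophage score, 3 among those of the clock activating arm and 0 among those of the adipocyte score. Quantile normalization gave 7304 probes past the threshold, 4059 higher and 3245 lower, and the arrays below the lymphocyte gap gave 5364. Slow fibre levels were alike in animals of neighbouring numbers (correlation 0.552 over 298 pairs of consecutive numbers), and 3 of 100 shifts of the score along animal number gave at least as many probes as the real order, up to 6632. This points to a structure of the animals along their numbers.

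Most probes of the glycolysis and glycogen list were higher with the clock activating arm, and all of the macrophage and lymphocyte lists lower. Of glycolysis and glycogen probes, 57 of 66 were higher, and 58 adjusted over the list alone, as were 8 of 10 oxidative phosphorylation probes, 22 of 27 proteasome probes, 15 of 17 fatty acid oxidation probes, 7 of 9 probes of the clock repressed arm and 6 of 8 of the glucocorticoid response, by either count. Lower, by either count, were 16 of 16 macrophage probes, 10 of 10 lymphocyte probes, 18 of 21 interferon response probes, 18 of 21 extracellular matrix probes and 12 of 15 slow fibre probes. Among single genes over 319 arrays, the ribosomal protein gene Rpl3 was lower by -0.48 ± 0.027 (SE) per SD, the cell cycle phosphatase Cdc25b by -0.27 ± 0.016, the immunoproteasome subunit Psmb10 by -0.26 ± 0.015 and Pafah1b3 by -0.26 ± 0.015. Vmac, Prim2, Gstt2, Erg28, D10Wsu102e and Pdk3 were lower, with slopes from -0.23 to -0.18. Asb12 was higher by 0.22 ± 0.013, the phosphatase Dusp13 by 0.17 ± 0.010, and Mroh8, Eri3, Creld1, Ubqln4, Ndel1, Ppp2r2d, Tesk1 and Npepl1 by 0.16 to 0.11. All had an adjusted p of at most 4.16e-41.

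Over all probes 16355 of 23185 passed with the clock activating arm, 10454 higher and 5901 lower. The share higher was 63.9%. It was 49.6% with array medians subtracted (7857 higher and 7987 lower) and 46.6% with the first principal component removed (5527 and 6323). An absolute r over 0.5 was reached by 2100 probes, of which 1508 were also among those of the macrophage score. That count was 972 with array medians subtracted, 658 with quantile normalization, 5 with the first principal component removed and 6 on the arrays below the lymphocyte gap, where 9743 probes passed the threshold.

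A locus that segregates in an F2 intercross gives genotypes in the ratio 1:2:1, and the shape of each probe's values was compared with such a mixture. Of 23190 probes, 92 were called, and these covered 40 named genes with a median spacing of 0.75 log2 units between components. Whether called probes shared a locus was not tested, so these counts are not of separate loci. Over 319 arrays the spacing was 0.76 (component SD 0.19) for Wtap, a subunit of the RNA methyltransferase complex, with a BIC gain of 87.4. It was 0.40 (0.10) for Hars, the histidyl-tRNA synthetase, with a gain of 83.0, 0.51 (0.13) for the nuclear import receptor Ipo8 with 81.9, and 0.49 (0.13) for the dynein light chain Dynlt1b with 76.9. Gfer, of the mitochondrial import pathway, had a spacing of 1.03 (0.25) and a gain of 93.0, Nprl2 0.42 (0.11) and 75.8, Alad, of haem synthesis, 0.75 (0.21) and 56.4, Rps3 0.88 (0.25) and 51.5, Mknk1 0.44 (0.12) and 51.0, and Rpgrip1 2.90 (0.54) and 53.4.

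The other 5 of the 15 named genes with the largest gain were better fitted by a mixture of 2 equal components, by a BIC difference of -110 for Pttg1, -421 for Eif2s3y, -293.5 for Kdm5d, -173 for Ccl27a and -25.4 for Bank1. Eif2s3y and Kdm5d are Y-linked. Among all called probes 20 were of this kind, which left 72. These still held Olfr707, Lhx1 and Tmprss11a, with spacings of 4.85, 4.84 and 4.99 log2 units and values at both limits of the scale. Probes cut off at limits were not simulated, so the simulated shapes do not cover such calls. Of 13 alternatives, Ipo8 was called in 13, Gfer, Wtap, Nprl2 and Mknk1 in 12, Hars, Dynlt1b, Alad, Rps3, Ccl27a and Eif2s3y in 11, Pttg1 in 10, Kdm5d in 9 and Rpgrip1 in 8. Bank1 was called in 7 of 12. A spacing over 2.5 component SDs is looser than the main rule, and the settings on missing values left the values of these probes as they were. Those alternatives could not end a call and say nothing on how firm it is. Free weights include the 1:2:1 mixture as a special case, so a call kept under them says little. For Rpgrip1 the BIC difference from 2 equal components was only 0.284, and its call ended without arrays of outlying SD (gain -5.77), with the first principal component removed (-5.80), with blocks of animal numbers (-5.82) and below the lymphocyte gap (-5.59). Quantile normalization ended the calls of Wtap, Hars, Dynlt1b, Gfer, Alad, Rps3, Bank1, Kdm5d and Rpgrip1 and gave 28 probes in all, blocks of animal numbers gave 58, a spacing over 4 component SDs gave 19, and free weights, which admit skewed shapes, gave 13708. Of the genes on the parental strain list, Ifi202b was called, with a spacing of 1.42 (0.47) and a gain of 15.3, and in 8 of 13 alternatives. The gain was -5.79 for Apoe, -5.80 for the MHC gene H2-Ea, -5.83 for the endotoxin receptor Tlr4, -5.85 for Abcc6 and -5.95 for Nnt, none of which was called. With free weights Apoe and H2-Ea were called. As both parents lacked functional ApoE, the values of Apoe say nothing on a difference between them.

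**Figure D3:**
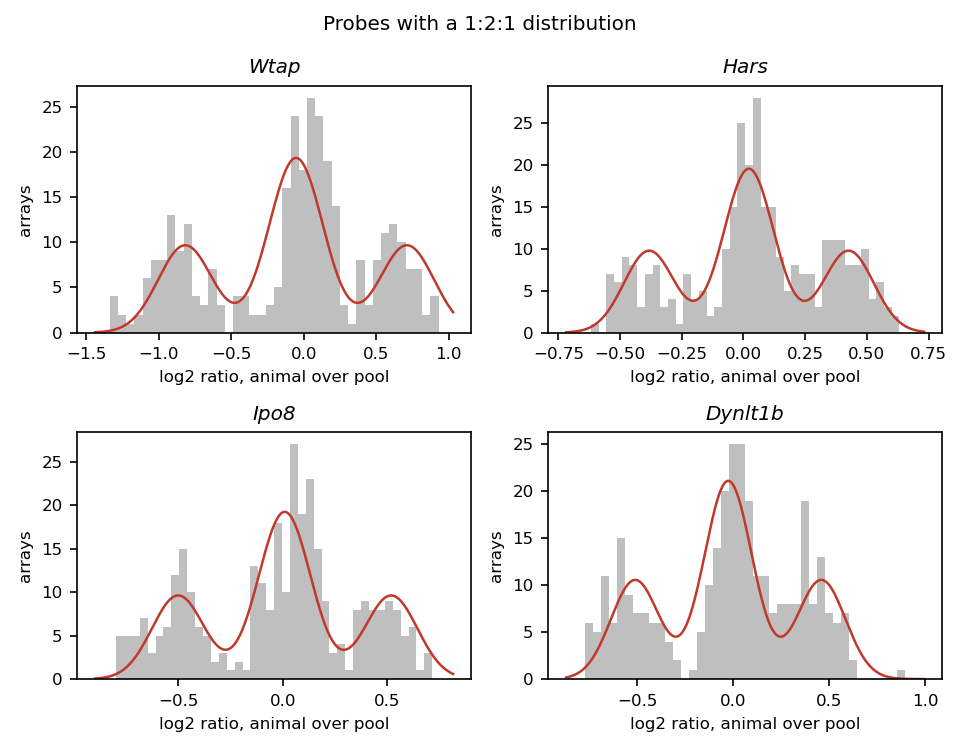
Histograms of the log2 ratio of animal over pool on 319 arrays for Wtap, Hars, Ipo8 and Dynlt1b, with the fitted mixture of 3 normal components in the ratio 1:2:1 as a line. The components are spaced by 0.76, 0.40, 0.51 and 0.49 log2 units.

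Genes next to each other on a chromosome varied together more than genes on different chromosomes, and the excess shrank with distance. Whether linked alleles or another cause made it was not tested. The mean absolute r across 319 arrays was 0.243 over 5760 pairs of adjacent genes, against 0.219 for genes on different chromosomes. It was 0.231 for genes 2 to 5 apart, 0.226 for genes 6 to 20 apart and 0.222 for genes 21 to 100 apart. Permuted positions gave at most 0.225, 0.222, 0.221 and 0.220, and the permutation p was 0.001 at each distance, the smallest that 1000 permutations can give. Without pairs whose symbols share their first 3 letters, such as the haemoglobin genes Hbb-b1 and Hbb-b2, adjacent genes had 0.239. The order covered 10586 genes, and pairs are not independent replicates.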

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

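Of 1962 results computed under an alternative, 1873 kept their direction and their side of the threshold or stayed within 1.5 times the main count, 49 were weaker, 12 stronger, 5 reversed and 23 moved. Of 952 alternatives for the genes named with the scores, 949 kept direction and call, 3 were weaker and 0 reversed. These genes had been picked for the largest t of the main fit, which favours calls that are kept. The macrophage and clock activating arm lists had 1 probe per gene, so the probe of largest SD could not change their fits. For the 1:2:1 calls of named genes, the settings on missing values and a spacing over 2.5 SDs could not end a call. These count as kept by construction. Free weights include the 1:2:1 mixture as a special case, so a call kept under them says little. Chosen after seeing the data were the settings with the arrays below the lymphocyte gap, with those below or above the interferon response gap, without probes at both limits and with 2 equal components. Removal of the first principal component gave all 5 reversals: a mean r of -0.00339 within the clock repressed arm list and, over all arrays, r of 0.0350 for glycolysis and glycogen with MHC class II, 0.109 for MHC class II with the clock repressed arm, -0.0369 for MHC class II with cell cycle and 0.0325 for the clock repressed arm with cell cycle. It also gave 125 of 300 pairs of list scores past the threshold (227 in the main result), 8113 probes with the macrophage and 5793 with the adipocyte score, and 180, 210 and 5 probes with an absolute r over 0.5 for the macrophage, adipocyte and clock activating arm scores. On the arrays below the lymphocyte gap these counts were 143 pairs, 9558 probes with the adipocyte, 5364 with the slow fibre and 9743 with the clock activating arm score, and 899, 474 and 6 probes with an absolute r over 0.5 for macrophage, adipocyte and clock activating arm. Quantile normalization gave 574 and 658 such probes for adipocyte and clock activating arm, 7304 probes with the slow fibre score and 28 with a 1:2:1 distribution. Subtraction of array medians gave 1390 and 972 probes with an absolute r over 0.5 for adipocyte and clock activating arm, and the first principal component of the adipocyte list gave 1784. For the 1:2:1 distribution, a spacing over 4 SDs gave 19 probes and blocks of animal numbers 58. Free weights gave 13708, since by construction they admit any weights. Apart from free weights and the stricter spacing, the cause was not tested. Xist as a covariate was not run, as no named probe measured it. For arrays, their number limits the precision.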

Other observations

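Tests chosen only after the result was seen were those of lymph node tissue and of a batch among the lymphocyte genes, both tests of the probes without values, the tests of chance order and of a batch on all probes for the slow fibre genes, the shuffled and shifted orders of the 4 scores, the probes alike in neighbouring numbers, the shares of single genes, and the relation of Nnt and Paip1. Of 79 named probes whose values fell in clusters more than 6 SDs apart, 3 were picked because the smaller cluster held near 25% of arrays, so the exact binomial tests of their shares against 25% (p = 1 for Pttg1, 0.401 for Paip1 and 0.365 for Ccl27a) decide nothing. Pttg1, which encodes securin, had a median log2 ratio of -3.09 on 79 arrays and 0.19 on 240, so that 24.8% of arrays were low (95% Clopper-Pearson interval 20.1 to 29.9). A probe of Paip1, a partner of the poly(A)-binding protein, lay at -2.90 on 73 arrays and 0.27 on 246 (22.9%, interval 18.4 to 27.9), and Ccl27a at -2.06 on 87 and 0.25 on 232 (27.3%, interval 22.5 to 32.5). Nnt, the mitochondrial transhydrogenase next to Paip1 in gene order and known to carry a deletion in C57BL/6J, was lower on 93 arrays (29.2%, interval 24.2 to 34.5) when split the same way, with a separation of 3.02 SDs, below the highest of 3.25 in simulated normal samples, and 299 arrays lay on the same side for both genes, including all 73 low in Paip1. Within the 246 arrays above the Paip1 gap their r was 0.625 (rho 0.600, 0.619 without the 2 farthest arrays, both permutation p 1e-05, the smallest possible, adjusted over 2 relations 2e-05). Within the 73 below it r was 0.0956 (p = 0.411, adjusted p = 0.411) and rho 0.168 (p = 0.155, adjusted p = 0.155), with 0.193 without the 2 farthest.

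Other genes had clusters of other sizes. Skap2 had -4.30 on 214 arrays and 0.35 on 105 (32.9%, interval 27.8 to 38.4). The skin protein Lor was high on 28 arrays and the plasma protein Plg on 15, which is the smallest cluster that was allowed. The correlation between consecutive animal numbers was 0.542 for Skap2, and 0.540 with the Y-linked level removed. No explanation was tested for Skap2, Lor and Plg.

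For each of the 4 scores, none of 100 freely shuffled orders gave as many probes past the threshold as the real one, by an ordinary regression. This shows only that many probes shared variation across arrays with the score. Scores of random lists were not compared in this way, so it does not set these lists apart from other genes. The real counts and the highest of the 100 other orders were 17494 and 4 for macrophage, 15382 and 3 for adipocyte, 3269 and 89 for slow fibre and 16354 and 2664 for the clock activating arm. Free shuffles break the likeness of animals of neighbouring numbers. Of 100 shifts along animal number, which keep it, 0 gave as many probes for macrophage (highest 510), adipocyte (1778) and the clock activating arm (4365). For slow fibre 3 did, and the highest, 6632, lay above the real count, which points to a structure of the animals along their numbers.

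Lymphocyte genes were high on 59 arrays and low on 260. The design gives no group, so no biological explanation was tested. Lymph node tissue among the muscle is a candidate source. Of 16 lymph node genes listed before the test, 9 were measured and not on the lymphocyte list, which holds 2 others. Their median r with the lymphocyte score was 0.631 within the 59 arrays (0.373 within the 260). A share of 0.0002 of random lists gave as high a median. The random genes were matched on SD only, so this share cannot tell lymph node from another source of lymphocytes. SDs were 1.71 for Cxcl13, 1.60 for Ltb and 1.55 for Cxcr5. Within the 59 arrays r was -0.329 for Ccr7 and 0.0689 for Tnfrsf13b. Blood left in the muscle is argued against as the source, since the erythroid score had r = -0.222 (95% interval -0.452 to 0.0366, permutation p = 0.0921; rho -0.146, p = 0.267; -0.0519 without the 2 farthest arrays) with the lymphocyte score within the 59. A batch that follows animal number cannot be told apart, as 45.8% of the 59 numbers had no neighbouring number above the gap (95% interval 32.7 to 59.2). This share lay between the set limits, against a median of 66.1% in shuffled orders. Other lymphoid tissue, such as spleen, was not tested. The macrophage genes Marco and Spic, picked after the values were seen, stood above their own gaps on 57 and 55 arrays. Whether these were the same arrays was not compared.

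Probes left out for missing values held abundant muscle transcripts, among them Tnnt3, Tnni2, Mylpf, Pvalb, Eno3, Pgam2 and Tpi1. No biological explanation was tested. Saturated spots removed before deposit may account for this but cannot be told apart from other causes, since the lists compared were grouped after the probes were seen and the comparison restates the pattern: 28 of 173 probes of the slow fibre, fast fibre, oxidative phosphorylation, glycolysis and ribosomal protein lists were left out against 6 of 385 of the other lists, an odds ratio of 12.1 (95% interval 4.80 to 36.6, Fisher's exact p = 2.41e-10), with 0 of 15 in the slow fibre list. Removal of spots near background is argued against only for probes of olfactory, vomeronasal and taste receptors. Of these 0 of 436 were left out against 121 of 13251 other named probes, an odds ratio of at most 0.936 (upper end of the 95% interval, Fisher's exact p = 0.0348). It stays open for other probes, as Pde6g, Fgf18, Tssk3 and Pax3, on none of the lists compared, were also left out. Blanks too few for a probe to be left out were not counted, and Olfr707 had values on 306 of 319 arrays. Whether the other values of such genes are compressed stays open.

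Slow fibre genes were alike in animals of neighbouring numbers, with a correlation of 0.552 between 298 pairs of consecutive numbers (0.559 without the sample that has a different number in its title). Chance order is argued against, with a permutation p of 1e-05, the smallest that 100000 orders can give, and a highest shuffled value of 0.239. Animals of the same sex numbered in runs are argued against as the whole cause, since the correlation was 0.560 with the Y-linked level removed. A batch effect on all probes is argued against as the whole cause, since the other coherent lists had a median of 0.156, up to 0.374 for the clock activating arm, but a batch on part of the probes stays open: of 55 probes at 0.5 or more, 8 were of the list, 3 of the Y chromosome and 44 of neither, and of these 44, 13 stayed there with the Y-linked level removed, among them Skap2 (0.540), and 20 fell under 0.2. Of the 44, 4 had an absolute r over 0.5 with the slow fibre score itself and so do not stand apart from it. No biological explanation was tested, and a muscle or a part of it that was dissected differently over time may remain as an untested hypothesis.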
